A study of Rattus norvegicus with 19 samples.

How the data were processed

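Liver RNA from 19 adult male Wistar rats was measured on Agilent rat 2-colour arrays. Per the labels, the rats received 1 of 3 diets for 4 months from 8 weeks of age. The control diet (7 rats) gave 70% of its energy as carbohydrate, 10% as fat and 20% as protein. The high protein diet (6 rats) gave 45% as carbohydrate, 10% as fat and 45% as protein, mainly casein. The high fat diet (6 rats) gave 20% as carbohydrate, 60% as fat and 20% as protein. The rats were killed in the fed state in the early morning, and 1000 ng of RNA of each was labelled. Each array carried the RNA of 1 rat in Cy5 against an equimolar pool of liver RNA in Cy3, with no dye swaps. The labels give separate animals and no pairing. The replicate numbers were checked for hidden pairs, after group means were removed. The 18 pairs of like-numbered rats in different diet groups had a mean correlation of -0.0104, against 0.0013 for the 102 unlike-numbered pairs. Of 19 rats 5 correlated best with a like-numbered rat of another group, and no chance level was computed for this count. No pairing was used.

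Per the file headers, the deposited scanner files give signal and local background as intensity, read with Agilent Feature Extraction 10.5.1.1, as mean signals and as processed signals after its background and dye corrections. The authors also deposited a series matrix of log2 values for 22764 features per array. Each of its columns had a median of 8.20, so the authors had brought the arrays to a common median. Within an array these log2 values followed Cy5. Across arrays, after each feature was centred, they followed the Cy5 to Cy3 log ratio (r across features between 0.985 and 0.998), so higher values stand for higher expression in the animal. The steps behind this matrix are not stated. It served as an alternative, and the main values were computed from the mean signals.

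Probes were named through the reference annotation. Of 41012 non-control probes, 11006 were named by accession, 5122 by symbol, 3554 by a synonym and 923 by the name in the files alone, and 20407 had no gene name. Background medians were subtracted by the normexp method with an offset of 50, and log2 ratios of Cy5 to Cy3 were normalised by loess within each array, with control spots given no weight and no step between arrays. Spots marked as outliers by the scanner software were dropped and spots of 1 probe were averaged. A probe was kept where Cy5 was well above background on at least 6 of 19 arrays, which left 25292 probes. A gene was represented by its kept probe with the highest mean signal, and probes without a gene name stood for themselves. This gave 22184 features, 11287 named genes and 10897 unnamed probes, all called genes in counts over every feature. For 227 features at least 1 of 19 log ratios was missing, 231 values in all.

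The background step was changed after results had been seen. As planned, normexp was first fitted on every spot. On 4 arrays (control 6, control 7, high protein 4 and high protein 5) 5 to 10 spots lay under local background far brighter than the spot, and these spots set the fit. The fitted Cy5 background mean lay between -984 and -298 on these 4 arrays and between -26.2 and -4.61 on the other 15, which flattened the log ratios of the 4 arrays. The 40 spots on 5 arrays whose local background exceeded their signal by more than 50 were therefore dropped and kept from setting the fit. The fitted means then lay between -22.7 and -4.07. The first version is kept as an alternative. Further alternatives on control 7, which its results had prompted, were dropped with it.

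Differential expression was tested in R 4.3.3 with limma 3.58.1: 1 linear model over the 3 diet groups, contrasts, and moderated tests with 16 residual and 3.25 prior degrees of freedom, all two-sided. P values were adjusted by the Benjamini-Hochberg method over the 22184 features, and a call needed an adjusted p under 0.05. A moderated F test asked whether any diet differed. Fold changes are log2 and are given with the standard error of the model (SE). They are named as the first diet over the second. The 33 gene lists with at least 5 measured members cover liver metabolism, stress and signalling pathways and markers of other cell types. They were fixed before the data were examined, as were the tests, all but 2 of the alternatives and the rule for named genes. Each list was tested with camera at a preset correlation between genes of 0.01, adjusted over the 33 lists, and with fry and camera with an estimated correlation as alternatives. Within each list, p values were also adjusted over the list alone. Named genes are the 10 largest rises and the 10 largest falls among called features with a gene name in each comparison, so an unnamed probe may have changed more, up to 4 members with the smallest p of each list discussed, and Cyp7a1, Fasn, Scd, Pck1, Cpt1a, Sds, Tat, Phgdh and Igfbp1 in every comparison. Some single-gene results are not reported here, and these genes stay in all counts and list tests but not in the checks of single genes.

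The analysis was tested on simulated data, in which known changes were added to independent normal noise with the spread of each feature. For the high protein comparison it recovered 86.6% of changes of 1.5-fold, 94.0% of 2-fold and 100% of 4-fold. For the high fat comparison these shares were 85.1%, 94.0% and 100%. False calls made up 6.50% and 7.92% of the calls in these comparisons, and 4.80% between the diets. The simulated noise of a feature had the same spread on every array. It gave 200 calls for high protein, against 92 in the real livers. The shares recovered may therefore overstate what was recovered from the real arrays, which differed in spread. The number of arrays limits the precision, and their slides were checked as batches. The arrays sat on 5 slides scanned on 1 day. Slide gave 0 called features by limma's F test within diet groups, and array position gave 0. At an unadjusted p under 0.05 they gave 1931 and 1229, against 1109 expected by chance, so small slide effects were not excluded. Control and high protein rats shared 3 slides, control and high fat rats shared 3, and high protein and high fat rats shared only slide 1. Alternatives changed the signal used, background, scaling, filters, choice of probe, blocking by slide or replicate, arrays included, array weights, variance shrinkage and list test. Paralogs with similar sequences, such as Gstm4 and Gstm7 or Scd and Scd2, may share probe signal, which was not tested. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.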

Results

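Livers of 19 rats in 3 diet groups were profiled, 7 on the control diet, 6 on the high protein diet and 6 on the high fat diet. Each value is the log2 ratio of 1 rat's RNA to a pool of liver RNA. Between 54.2% and 67.5% of the spots of an array were well above background in Cy5 (the rat) and between 47.2% and 55.1% in Cy3 (the pool). The standard deviation of the log ratios of an array lay between 0.20 and 0.29 except in control 6, where it was 0.45. Over all 3 groups, 1460 of 22184 genes differed by limma's F test, among them 814 named genes. The gene positions used by the arrays refer to the rat genome build rn4.

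The comparison of high protein with control livers asked how liver expression differed when protein replaced part of the carbohydrate at the same share of fat. Genes of amino acid breakdown and of the urea cycle, which turns amino nitrogen into urea, were higher in the high protein livers by camera (medians 0.20 and 0.32), but not with an estimated correlation (adjusted p = 0.140 and 0.148). Of 54 and 8 measured members 10 and 2 rose over all genes. The urea cycle gene Asl rose by 0.97 ± 0.13 (log2, SE, n = 6 high protein and 7 control, adjusted p = 0.0035), and every high protein liver lay above every control liver. Sds, which deaminates serine, rose by 1.41 ± 0.30 (adjusted p = 0.0452) with overlap between the groups. In all, 92 genes differed (61 higher and 31 lower, 48 and 12 of these were named), and 9 of them by over 2-fold. The balance of rises and falls was not stable: 26 of 55 genes were higher with the background fit first planned and 70 of 78 with the deposited values. At an unadjusted p under 0.05 the number was 3166.

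Of 54 measured genes of amino acid catabolism, 10 rose and none fell over all genes; adjusted over the list alone, 28 rose and 1 fell. Their median was 0.20 (camera adjusted p = 5.51e-20, adjusted p = 0.140 with an estimated correlation). Besides Sds they included Acmsd, an enzyme of tryptophan breakdown (1.26 ± 0.24, adjusted p = 0.0315), Hpd of tyrosine breakdown (0.77 ± 0.12, adjusted p = 0.0124) and Cbs of the transsulfuration pathway (0.62 ± 0.10, adjusted p = 0.00864). Hal, which breaks down histidine, rose by 0.57, and the aminotransferase genes Got1 and Gpt rose by 0.93 and 0.71. Acmsd, Hpd, Cbs, Hal, Got1 and Gpt were higher in each of the 6 high protein livers than in any control. Of 8 urea cycle genes, Asl and Cps1 (0.62 ± 0.13, adjusted p = 0.0328) rose, and 5 rose adjusted over the list alone. The median of this list was 0.32 (camera adjusted p = 3.51e-06, adjusted p = 0.148 with an estimated correlation). Ass1 differed by 0.71 ± 0.17 and did not pass over all genes (adjusted p = 0.083), but did in 3 of 19 omissions of 1 rat. Of 34 genes of conjugation and glutathione use, 3 rose (6 adjusted over the list alone). The median was 0.10 (0.07 without high protein 3 and 0.19 with the deposited values, camera adjusted p = 0.000163, adjusted p = 0.145 with an estimated correlation). The members that rose were the glutathione transferase genes Gstm4 (1.01 ± 0.12, adjusted p = 0.00107) and Gstm7 (0.69 ± 0.12), and Nnmt, which methylates nicotinamide (0.73 ± 0.13).

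A further 5 lists passed camera although none of their members passed over all genes. Oxidative phosphorylation had a median of 0.06 over 44 genes (0.04 without control 6, 4 higher adjusted over the list alone, camera adjusted p = 0.000699, adjusted p = 0.668 with an estimated correlation). The proteasome had 0.10 over 30 genes (0 adjusted over the list alone, camera adjusted p = 0.00102, adjusted p = 0.668 with an estimated correlation). Cholesterol synthesis and uptake had 0.20 over 26 genes (2 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.00531, adjusted p = 0.691 with an estimated correlation). Xenobiotic phase I enzymes had 0.11 over 32 genes (3 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.034, adjusted p = 0.668 with an estimated correlation). Lymphocyte markers had -0.53 over 15 genes (0 adjusted over the list alone, camera adjusted p = 0.0035, adjusted p = 0.668 with an estimated correlation). Control 6 had a lymphocyte marker median of 2.56, against -0.95 to -0.48 in the other 18 livers. Control 6 was also the lowest of the 19 livers for amino acid catabolism (-0.39), the urea cycle (-0.52), conjugation (-0.19), oxidative phosphorylation (-0.15) and cholesterol synthesis (-0.54). The lymphocyte list no longer passed without control 6 (-0.06, adjusted p = 0.482), the cholesterol list without control 6 or high protein 1 (adjusted p up to 0.181, median 0.10 without high protein 1), and the xenobiotic list without control 2, 3 or 6 or high protein 3, 5 or 6 (up to 0.169). On slides 1, 4 and 5, which held both diets, the lymphocyte medians were 0.21, -0.21 and -3.54, the cholesterol medians -0.25, -0.13 and 0.71, and the xenobiotic medians -0.03, -0.02 and 0.25. The other 5 lists had 1 direction on all 3 slides. Control 6 was the only control on slide 5, so the values of that slide rest on this outlying liver. The cholesterol (0.04, adjusted p = 0.375) and xenobiotic (0.06, adjusted p = 0.22) lists did not pass with slide as a fixed block.

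Among the other large rises was Dnase2b, an acid endonuclease (1.18 ± 0.17, adjusted p = 0.00621). Among named genes the largest falls were those of Cib2 (-2.41 ± 0.39, adjusted p = 0.0124), the gap junction gene Gjb2 (-0.56 ± 0.09, adjusted p = 0.0124), the corepressor gene Ncor1 (-0.49) and the deubiquitinase gene Usp40 (-0.45). Smaller falls were those of the cell cycle inhibitor gene Cdkn2c (-0.45, -1.13 with processed signals), Smg1 of RNA decay (-0.38, -0.77 with processed signals), Slf2 (-0.32), Zfp281 (-0.28), Dennd4c (-0.26) and Plpp6 (-0.24). Of the 20 named calls of this comparison, 8 were lost with Cy5 alone, those of Dennd4c and Plpp6 among them (adjusted p = 0.383 and 0.672). The 20 named genes of largest change, chosen on these same livers, had the same direction on each of the 3 shared slides. For 15 of them the groups did not overlap, which fixed that direction in advance, and control 6 was the only control on slide 5. The tyrosine aminotransferase gene Tat (0.64 ± 0.19, adjusted p = 0.132), Cyp7a1 (1.01, adjusted p = 0.393, 0.62 without high protein 3), Scd (-0.64, adjusted p = 0.481), Phgdh (-0.71, adjusted p = 0.324, -0.36 without control 6), Fasn (0.28, adjusted p = 0.824), Cpt1a (-0.24, adjusted p = 0.583), Igfbp1 (0.19, adjusted p = 0.716) and Pck1 (-0.13, adjusted p = 0.799) did not pass. The count of 92 depended on single rats: it was 19 without control 1, 25 without control 2, 60 without control 5, 43 without control 6, 373 without control 7, 38 without high protein 1, 22 without high protein 2, 29 without high protein 4 and 18 without high protein 6. With slide as a fixed block 20 genes passed, and 14 of the 20 named calls were lost while the values stayed near those above: Sds at 1.70, Got1 at 1.07, Hpd at 0.73, Gpt at 0.62 and all 10 falls, with Cib2 at -2.20 and Gjb2 at -0.55. Those of Cps1 (0.65, adjusted p = 0.0932) and Gstm7 (0.67, adjusted p = 0.081) were lost as well. Omitting 1 rat kept 8 of the 20 calls throughout (Asl, Gstm4, Hpd, Nnmt, Dnase2b, Cib2 and Gjb2 among them). It ended the call of Sds in 13, of Cps1 in 10, of Gpt in 8, of Acmsd in 6, of Hal in 4, of Got1 in 3 and of Gstm7 in 1 of 19 omissions, and those of the other 8 falls in 5 to 15.

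**Figure D1:**
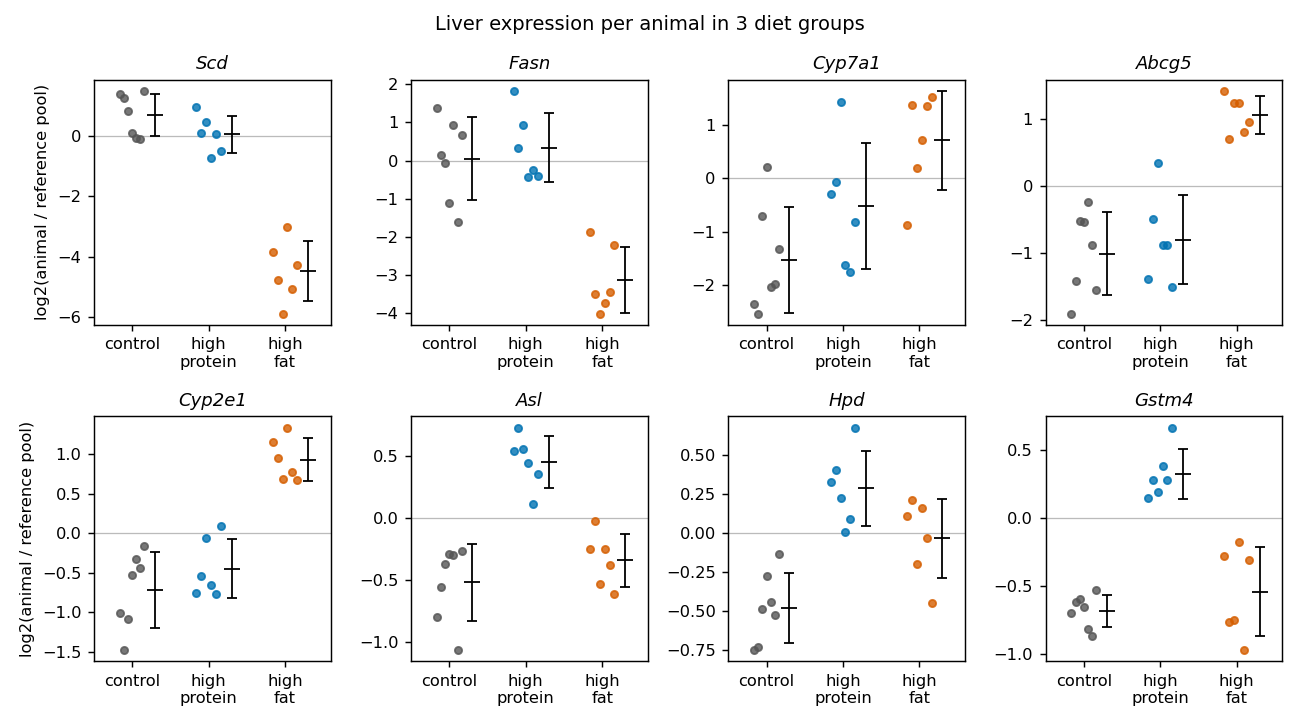
Log2 ratio to the reference pool (vertical axis, scaled per gene) of 8 genes in each of the 19 livers (points, by diet), with the mean and standard deviation of each group beside them. In high fat livers Scd and Fasn lay below, and Abcg5 and Cyp2e1 above, every control liver, while Asl, Hpd and Gstm4 in high protein livers lay above every control liver.

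The comparison of high fat with control livers asked how liver expression differed when fat replaced most of the carbohydrate at the same share of protein. Genes that make fatty acids and break down glucose were lower in the high fat livers, and genes that burn fatty acids, make bile acids or oxidise foreign compounds were higher. The call of the last list was lost with an estimated correlation without control 6 (adjusted p = 0.0886). The desaturase gene Scd (-5.17 ± 0.40, log2, SE, n = 6 high fat and 7 control, adjusted p = 6.56e-07) and the fatty acid synthase gene Fasn (-3.19 ± 0.49, adjusted p = 0.000889) fell, each below every control in all 6 high fat livers. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, rose by 2.24 ± 0.52 (adjusted p = 0.018) with overlap between the groups. In all, 809 genes differed (410 higher and 399 lower, 242 and 211 of these were named), 76 of them by over 2-fold.

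Of 22 genes of fatty acid synthesis, 15 fell (19 adjusted over the list alone) and none rose, with a median of -0.90 (camera adjusted p = 1.37e-24, adjusted p = 0.0252 with an estimated correlation). They included the elongase gene Elovl6 (-3.10 ± 0.57, other probe -1.45), Scd2 (-2.92 ± 0.22, other probes -0.28 and -0.04), Acly, which makes cytosolic acetyl-CoA (-2.16 ± 0.41), Me1, which makes NADPH (-2.12 ± 0.40), Acaca, the acetyl-CoA carboxylase (-1.87 ± 0.30, other probe -0.49), and Tkt of the pentose phosphate pathway (-1.02 ± 0.13). Of 14 glycolysis genes, 7 fell (10 adjusted over the list alone). The median was -0.34 (camera adjusted p = 1.06e-09, adjusted p = 0.0252 with an estimated correlation). Among the members that fell were the liver pyruvate kinase gene Pklr (-1.39 ± 0.18), Gpi (-0.61), Gapdh (-0.52) and Eno1 (-0.50). Of 10 gluconeogenesis genes, Mdh1 (-0.67) and Gpd1 (-0.60) fell (4 fell adjusted over the list alone). The median was -0.14 (camera adjusted p = 0.00534, adjusted p = 0.239 with an estimated correlation).

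Of 24 genes of mitochondrial fatty acid oxidation and ketogenesis, 10 rose (14 adjusted over the list alone) and none fell, with a median of 0.24 (camera adjusted p = 1.11e-12, adjusted p = 0.0221 with an estimated correlation). The gatekeeper gene Cpt1a rose by 0.82 ± 0.19 (adjusted p = 0.0156), Eci1 by 0.79, Decr1 by 0.56, Hadhb by 0.50 and Hadha by 0.40. Of 22 genes of bile acid synthesis and sterol transport, 5 rose (7 adjusted over the list alone). The median was 0.21 (camera adjusted p = 6.83e-08, adjusted p = 0.0165 with an estimated correlation). Besides Cyp7a1 they were the sterol exporter gene Abcg5 (2.06 ± 0.28, adjusted p = 0.000353), the oxysterol hydroxylase gene Cyp7b1 (1.84 ± 0.21, adjusted p = 8.25e-05), Cyp8b1 of cholic acid synthesis (0.83 ± 0.19) and Slc27a5 of bile acid activation (0.67 ± 0.13). Of 32 xenobiotic phase I genes, 9 rose and 1 fell (18 and 1 adjusted over the list alone). The median was 0.26 (camera adjusted p = 9.5e-11, adjusted p = 0.0381 with an estimated correlation). Cyp2e1 rose by 1.65 ± 0.20, Cyp1a2 by 1.24 ± 0.21, the nuclear receptor gene Nr1i3 by 1.19 ± 0.22 and Fmo1 by 1.18 ± 0.20.

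The other lists that passed camera did so with few members past the test over all genes. Of 26 PPAR alpha target genes of peroxisomal and omega oxidation, Ech1 (0.90) and Creb3l3 (0.41, lost in 14 of 19 omissions of 1 rat) rose and Angptl4 (-0.79, lost without high fat 2 or high fat 4), an inhibitor of lipoprotein lipase, fell (8 rose and 2 fell adjusted over the list alone). The median was 0.21 (camera adjusted p = 0.000329, adjusted p = 0.333 with an estimated correlation). Of 12 male-biased liver genes Cyp3a2 rose by 1.27, or 0.77 with Cy5 alone (2 adjusted over the list alone). The median was 0.21 (camera adjusted p = 0.00054, adjusted p = 0.239 with an estimated correlation). Of 21 genes of serine synthesis and the amino acid response Nupr1 (-0.80) fell (5 adjusted over the list alone). The median was -0.18 (camera adjusted p = 0.00255, adjusted p = 0.255 with an estimated correlation). Of 54 genes of amino acid catabolism 3 rose and Gldc of glycine cleavage (-0.60) fell (6 rose and 1 fell adjusted over the list alone). The median was 0.09 (camera adjusted p = 0.0112, adjusted p = 0.652 with an estimated correlation). Of 20 stellate cell and matrix markers Rgs5 (0.60) and Reln (0.52) rose (2 adjusted over the list alone). The median was 0.09 (camera adjusted p = 0.0153, adjusted p = 0.574 with an estimated correlation). Of 23 interferon response genes Ifi27l2b (-1.09) fell (2 adjusted over the list alone, median -0.16, camera adjusted p = 0.0195, adjusted p = 0.649 with an estimated correlation), and its other probe gave -0.0041. None of 15 lymphocyte markers passed (0 adjusted over the list alone). The median was -0.44 (camera adjusted p = 0.028, adjusted p = 0.690 with an estimated correlation). Control 6, with its lymphocyte median of 2.56, was the lowest of the 19 livers for fatty acid oxidation (-0.24), bile acid genes (-0.28) and amino acid catabolism (-0.39), and the highest for the serine list (0.24), whose median without it was -0.09. The lymphocyte list (adjusted p up to 0.959, median -0.0085 without control 6) no longer passed without control 6, high fat 1 or high fat 4, nor with slide as a fixed block (-0.27, adjusted p = 0.0807), and the amino acid list (up to 0.315) without control 6, high fat 2 or high fat 4. The interferon list (up to 0.0722) was lost without control 4, high fat 2 or high fat 4, and the stellate list (up to 0.258, median 0.02 without high fat 6) without control 3 or high fat 6. On slides 1, 2 and 3 the medians were -0.06, -0.18 and 0.03 for the interferon list, 0.01, -0.11 and 0.03 for lymphocytes, 0.01, -0.10 and -0.02 for the serine list and -0.22, 0.04 and 0.37 for the stellate list. The other 9 lists had 1 direction on these 3 slides.

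Large rises outside these lists were those of Sbspon (2.83-fold, adjusted p = 6.43e-05), the circadian deubiquitinase gene Usp2 (1.44 ± 0.36, adjusted p = 0.0277), the potassium channel gene Kcnh1 (1.43 ± 0.23, 2.23 with processed signals), the glutamate transporter gene Slc1a2 (1.41 ± 0.25), the medium-chain acyl-CoA ligase gene Acsm3 (1.39 ± 0.34) and the aldo-keto reductase gene Akr1c1 (1.32 ± 0.32). Large falls were those of the fatty acid binding protein gene Fabp5 (-3.13 ± 0.30), the lipid droplet gene Pnpla5 (-2.32 ± 0.38) and Ky (-2.03 ± 0.24, -3.95 with processed signals), whose signal was well above background in 5 of 6 high fat livers. The 20 named genes of largest change, chosen on these same livers, all had the same direction on the 3 shared slides. For 14 of them the groups did not overlap, which fixed that direction in advance. Phgdh (-0.79, adjusted p = 0.215, -0.44 without control 6), Igfbp1 (0.61, adjusted p = 0.143, passing without high fat 1), Tat (-0.38, adjusted p = 0.334), Pck1 (0.23, adjusted p = 0.641) and Sds (0.13, adjusted p = 0.879) did not pass. With slide as a fixed block 443 genes passed, and of the 20 named calls those of Cyp7a1 (1.80, adjusted p = 0.138), Usp2 (1.19, adjusted p = 0.26) and Acsm3 (1.07, adjusted p = 0.251) were lost, as were those of Slc27a5 (0.64, adjusted p = 0.0507), Creb3l3 (0.44, adjusted p = 0.1) and Angptl4 (-0.55, adjusted p = 0.253). Leaving out single rats ended the calls of Usp2 (5 of 19 omissions), Acsm3 (without control 1, high fat 3 or high fat 5) and Akr1c1 (without control 2, high fat 3 or high fat 5) and kept the other 17.

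**Figure D2:**
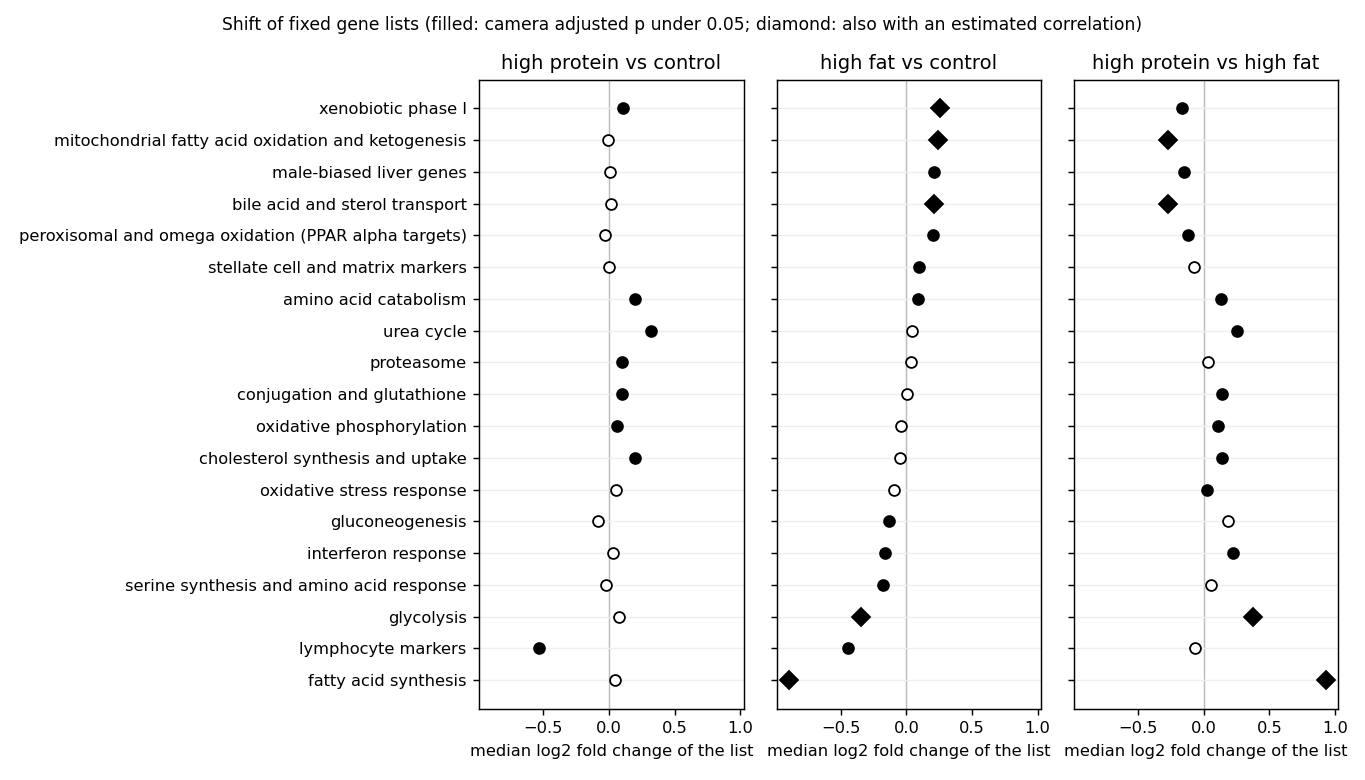
Median log2 fold change (horizontal axis) of each fixed gene list that passed camera in at least 1 of the 3 comparisons; filled points passed at the preset correlation, and diamonds also with an estimated correlation. Fatty acid synthesis lay at -0.90 in high fat against control livers and at 0.93 in high protein against high fat livers.

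The direct comparison of high protein with high fat livers asked where the effects of both diets differed from each other. Genes of fatty acid synthesis and glycolysis were higher in the high protein livers, and genes of fatty acid oxidation and bile acid synthesis in the high fat livers (adjusted p = 0.0359 with an estimated correlation for all 4 lists). In high protein against control livers none of these 4 lists passed camera. Their medians there were 0.05, 0.08, -0.0079 and 0.01 in this order (camera adjusted p = 0.684, 0.0659, 0.947 and 0.646). By camera genes of amino acid breakdown and the urea cycle were also higher with high protein and those of xenobiotic oxidation with high fat, but not with an estimated correlation (adjusted p = 0.339, 0.320 and 0.339). Scd differed by 4.53 ± 0.41 (log2, SE, n = 6 and 6, adjusted p = 7.84e-06) and Abcg5 by -1.85 ± 0.29 (adjusted p = 0.000534), in both with no overlap between the groups. In all, 1560 genes differed (804 higher and 756 lower in high protein livers, 505 and 354 of these were named), 89 of them by over 2-fold.

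Of 22 genes of fatty acid synthesis, 18 were higher with high protein (18 adjusted over the list alone). The median was 0.93 (camera adjusted p = 2.5e-22, adjusted p = 0.0359 with an estimated correlation). Fasn differed by 3.47 ± 0.51, Elovl6 by 3.13 ± 0.60, Scd2 by 2.56 ± 0.23 (other probes 0.28 and 0.38), Acly by 2.10 ± 0.43 and Me1 by 1.77 ± 0.41. Of 14 glycolysis genes, 8 were higher (11 adjusted over the list alone). The median was 0.37 (camera adjusted p = 1.17e-11, adjusted p = 0.0359 with an estimated correlation). Among the higher members were Pklr (1.25 ± 0.18), Gapdh (0.63) and the fructokinase gene Khk (0.60). Of 24 genes of fatty acid oxidation, 13 were lower (15 adjusted over the list alone). The median was -0.27 (camera adjusted p = 1.57e-09, adjusted p = 0.0359 with an estimated correlation), with Cpt1a at -1.07 ± 0.20 (adjusted p = 0.00212), Decr1 at -0.79 and Acadm at -0.48. Of 22 bile acid and sterol transport genes, 6 were lower (7 adjusted over the list alone). The median was -0.27 (camera adjusted p = 1.8e-05, adjusted p = 0.0359 with an estimated correlation), with Cyp7b1 at -0.92 and the bile acid importer gene Slc10a1 at -0.31. Cyp7a1 differed by -1.23 ± 0.54 and did not pass (adjusted p = 0.206).

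Of 54 genes of amino acid catabolism, 15 were higher (18 higher and 1 lower adjusted over the list alone). The median was 0.13 (camera adjusted p = 2.49e-06, adjusted p = 0.339 with an estimated correlation). Acmsd differed by 1.56 ± 0.25, Sds by 1.28 ± 0.31 (adjusted p = 0.0169), Got1 by 1.19 ± 0.17, Tat by 1.02 ± 0.20 (adjusted p = 0.00285), Gldc by 1.00 ± 0.12 and Hal by 0.86 ± 0.11. Of 8 urea cycle genes Ass1 (1.03 ± 0.18), Asl (0.80 ± 0.14) and Cps1 (0.60 ± 0.13) were higher (3 adjusted over the list alone). The median was 0.25 (camera adjusted p = 0.000637, adjusted p = 0.320 with an estimated correlation). Of 44 genes of oxidative phosphorylation 5 were higher, Uqcrc1 (0.49) and Atp5f1a (0.36) among them (8 adjusted over the list alone). The median was 0.11 (camera adjusted p = 4.04e-05, adjusted p = 0.449 with an estimated correlation). Of 32 xenobiotic phase I genes 9 were lower, including Fmo1 (-1.14) and Nr1i3 (-1.09) (11 lower and 1 higher adjusted over the list alone). The median was -0.17 (camera adjusted p = 0.000304, adjusted p = 0.339 with an estimated correlation). Of 34 conjugation genes, 5 were higher, Nnmt (0.89) and Gstm4 (0.87) among them, and 3 lower, Sult1e1 (-0.75) among them (6 and 3 adjusted over the list alone). The median was 0.14 (camera adjusted p = 0.0132, adjusted p = 0.320 with an estimated correlation).

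Of 23 interferon response genes 3 were higher (6 adjusted over the list alone). The median was 0.22 (camera adjusted p = 0.000304, adjusted p = 0.409 with an estimated correlation). The higher members were Ifi27l2b (1.63 ± 0.20), whose other probe gave -0.02, Rig1 (0.49) and Ifi27 (0.42). Of 26 genes of peroxisomal and omega oxidation 4 were lower, Vnn1 (-1.53 ± 0.24), Cyp4a8 (-1.40 ± 0.39), Ech1 (-1.09) and Creb3l3 (-0.61), and 1 was higher (3 higher and 6 lower adjusted over the list alone). The median was -0.12 (camera adjusted p = 0.00466, adjusted p = 0.449 with an estimated correlation). Of 26 cholesterol genes Mvd (0.95), Pmvk (0.83) and Nsdhl (0.48) were higher, each call lost in 3 or more omissions of 1 rat (5 higher and 1 lower adjusted over the list alone). The median was 0.14 (camera adjusted p = 0.0132, adjusted p = 0.756 with an estimated correlation). Of 19 oxidative stress genes 2 were higher, Keap1 (0.26, lost in 7 of 19 omissions) among them (2 adjusted over the list alone). The median was 0.03 (camera adjusted p = 0.0326, adjusted p = 0.320 with an estimated correlation). Of 12 male-biased genes Cyp3a2 (-1.24, -0.68 with Cy5 alone) was lower (2 adjusted over the list alone). The median was -0.15 (camera adjusted p = 0.0336, adjusted p = 0.449 with an estimated correlation). The cholesterol list no longer passed without high protein 1, high fat 2 or high fat 3 (adjusted p up to 0.131, median 0.05 without high protein 1), the oxidative stress list without high protein 4, high protein 6 or high fat 2 (up to 0.128, median -0.0028 and so turned without high fat 2), and the male-biased list without high protein 4, high fat 4 or high fat 5 (up to 0.128). These lists did not pass with slide as a fixed block either (0.10, adjusted p = 0.628; 0.07, adjusted p = 0.0835; -0.16, adjusted p = 0.0735).

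Further large differences were those of Fabp5 (3.50 ± 0.32), RGD1564391 (2.40 ± 0.37, 4.78 with processed signals, well above background in 3 of 6 high fat livers), Pnpla5 (2.05 ± 0.40), the retinal dehydrogenase gene Aldh1a1 (-1.81 ± 0.28), the thyroxine-binding globulin gene Serpina7 (-1.72 ± 0.26), Akr1c1 (-1.62 ± 0.33), Fabp7 (-1.55 ± 0.36), Ctdsp1 (-1.43 ± 0.28, other probe -0.13), Acsm3 (-1.38 ± 0.35) and Cyp2e1 (-1.38 ± 0.21). Igfbp1 (-0.42, adjusted p = 0.306), Pck1 (-0.36, adjusted p = 0.367) and Phgdh (0.09, adjusted p = 0.944) did not pass. Only slide 1 held both diets, with 2 high protein livers and 1 high fat liver. All 20 named genes of largest change, chosen on these same livers, kept their direction there. For 16 of them the groups did not overlap, which fixed that direction in advance. Of 14 lists 12 kept their direction on slide 1, and cholesterol synthesis (-0.14) and conjugation (-0.06) did not. With slide as a fixed block 343 genes passed, and of the 20 named calls 7 were lost, those of Acly (1.86), Elovl6 (2.41), Me1 (1.26), Pnpla5 (2.04), Acsm3 (-0.79), Ctdsp1 (-1.13) and Cyp4a8 (-1.97). The block also ended the calls of the list members Ass1 (0.97), Cps1 (0.67), Khk (0.46), Uqcrc1 (0.37), Atp5f1a (0.23), Mvd (0.71), Pmvk (0.59), Nsdhl (0.30), Rig1 (0.53), Ifi27 (0.44), Keap1 (0.22), Cyp7b1 (-0.66), Sult1e1 (-0.67), Creb3l3 (-0.58), Acadm (-0.45) and Slc10a1 (-0.34). Of the 20 named calls, that of Acsm3 was also lost without high protein 2 and that of Cyp4a8 in 8 of 19 omissions of 1 rat.

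Both diets were set against the same control livers, so their fold changes were compared with what shared controls give. Across genes, which are not independent replicates, both sets of fold changes had a correlation of 0.308 and a covariance of 0.00974, against a simulated covariance of 0.00952. Unchanged groups simulated against shared controls gave a mean correlation of 0.628 (0.0285 to 0.911), and with the controls divided between the diets the mean was 0.0197 (-0.136 to 0.138 over 70 divisions). In both comparisons 10 genes were higher and 5 lower, and none went opposite ways. Independent lists would share 1.13 and 0.558. Simulated unchanged groups shared at most 0 and 1, which is no test of the overlap because such groups have few calls to share. With the controls divided between the diets, 0 to 12 genes were higher in both comparisons (mean 1.23), 0 to 4 lower (mean 1.09) and 0 to 34 went opposite ways (mean 1.81). These divisions left fewer controls per diet, and the number of calls varied widely between the divisions. Why it varied was not tested. On average 79.7 genes were called with high protein (0 to 890) and 466 with high fat (104 to 1106). Their overlaps are therefore not on the same scale as the overlap with all controls. The 9 named genes were Gstm7 (0.69 with high protein and 0.71 with high fat), Rgs5 (0.45 and 0.60), Slc43a1 (0.51 and 0.56), Rnd2 (0.48 and 0.43), Dap (0.39 and 0.34), RGD1564906 (0.33 and 0.31), Cib2 (-2.41 and -1.65), Gjb2 (-0.56 and -0.51) and Cdkn2c (-0.45 and -0.44). In high fat livers the call of Cib2 was lost without high fat 2 (adjusted p = 0.0561) and that of Cdkn2c with slide as a fixed block (-0.42, adjusted p = 0.0695), and single values of Slc43a1, Rnd2, Dap and RGD1564906 were not followed over the alternatives. The other 6 were unnamed probes. Some of these genes were named for this overlap after their values were seen. The overlap of 15 was 5 without control 1, 6 without control 2, 49 without control 7, 7 without high protein 1, 7 without high protein 2, 9 without high protein 4, 5 without high protein 6 and 4 with slide as a fixed block.

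Of the marker lists of cell types other than hepatocytes, only those of lymphocytes and stellate cells passed camera, as given above for each comparison. Markers of Kupffer cells, endothelial cells, cholangiocytes, erythroid cells, adipocytes and pancreas or gut passed camera in none of the 3 comparisons, where the lowest adjusted p was 0.591, 0.182, 0.378, 0.0715, 0.139 and 0.374.

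**Figure D3:**
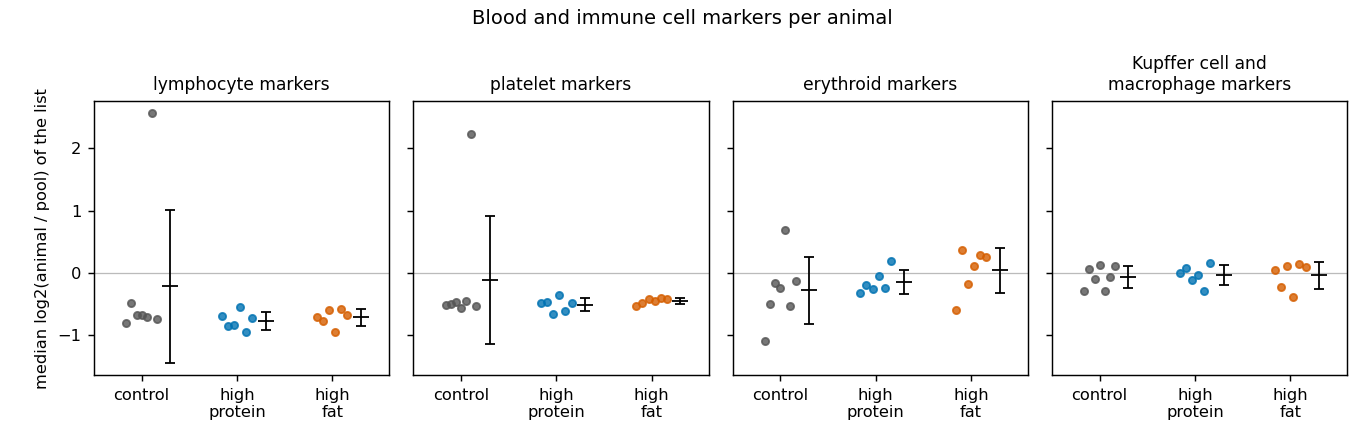
Median log2 ratio to the reference pool (vertical axis) of 4 marker lists in each of the 19 livers (points, by diet), with the mean and standard deviation of each group. Control 6 lay at 2.56 for lymphocyte and 2.23 for platelet markers, above the other 18 livers, and within their range for erythroid and Kupffer cell markers.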

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

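All tests of control 6 in this part were chosen only after the result was seen, while the tests of other groupings of the rats were planned. A sample is listed here when it lay far from the others of its own diet group for the size of that group. Chance alone gives about 1 such sample in 20 groups. Of 387 checks 24 gave one, and 18 of these were single genes out of 348 gene by group checks. The single genes were thus about as many as chance gives.

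Control 6 stood apart from the other 6 controls. The spread of its log ratios was 0.45, its mean correlation with its own group was -0.18, and 986 features lay over 1 log2 unit above the mean of the other controls, against 14 to 56 for the other control rats. Its lymphocyte marker median was 2.56 and its platelet marker median 2.23, with Cd3g 6.12, Gzmk 5.31, Cd3d 5.15 and the abundant Cd74 1.73 above the other controls. The platelet list of 4 genes was written after genes of this kind had been seen, left those genes out, and included Itgb3, which differed by 0.15.

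Blood left in the tissue would have raised erythroid markers too, but their median was -0.28 relative to the other controls and within the range of the other 18 livers, with the abundant Hbb at -0.13 and Alas2 at -0.38. Fewer hepatocytes with all other cells alike would have raised the markers of every other cell type, but the highest difference among Kupffer cell, stellate cell, endothelial and cholangiocyte markers was 0.0014. A wrong group label would have placed control 6 near a diet group, but it lay 0.343 of the way to the high fat group. That was further than any other control (-0.187 to 0.247). Toward the high protein group control 6 lay 0.0068 of the way, while control 7 lay 0.392 of the way. Lymphocyte-rich tissue or cells sampled with this liver may have brought these transcripts, which was not tested beyond the marker lists, and the design gives no biological explanation to test. Without control 6 the high protein comparison had 43 genes in place of 92 and the high fat comparison 913 in place of 809.

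Among 100 groupings of the same sizes, the real one included, only the real grouping (1) gave as many genes in each of the 4 tests. This argues against a random division of the rats, as far as 100 groupings can show. The regrouping ignored slide, so it could not tell diet from slide. The real count was 92 and the highest other 2 for high protein against control, 809 and 6 for high fat against control, 1560 and 1 for high protein against high fat, and 1460 and 6 for any diet.

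Other single values far from their group were in control 6 Cps1 (-0.73), Phgdh (2.05) and Slf2 (0.54), in control 5 Ghr (0.18) and Nqo1 (0.0084), and in control 7 Ky (1.68). In high protein 1 they were Fabp5 (1.74), Mvd (1.33) and Pck1 (-1.33), in high protein 2 Reln (-0.0487), in high protein 3 Gldc (0.0034) and Usp2 (1.43), and in high protein 4 Chac1 (1.08). In high fat 1 it was Decr1 (0.64), in high fat 3 Kcnh1 (0.13), in high fat 4 Cyp8b1 (-0.66) and Sesn2 (-0.71), and in high fat 6 Gpt (-1.06). High fat 4 also had the widest log ratios of its group (standard deviation 0.29), and high fat 6 the highest stellate cell marker median (0.45).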

How the results depend on the processing

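The alternative with the first background fit and the estimated correlation without control 6 were chosen after seeing the data; all others were planned. Over all alternatives the named genes kept direction and outcome, called or not, in 5534 comparisons, lost the call in 466, gained it in 7 and reversed in 8. Called lists kept direction and call in 1146 and lost the call in 114. These counts include genes never called, and omissions of rats outside the compared groups, which leave the fold change as it was. They therefore overstate how stable the calls were. High protein against control was the least stable count. Its 92 genes became 32 with only the compared groups, 45 with Cy5 alone, 53 with processed signals, 55 with the first background fit, 20 with slide as a fixed block, 162 with a replicate block, 234 with array weights and 18 to 373 without 1 rat, with 373 without control 7. High fat against control gave 443 with slide as a fixed block. High protein against high fat gave 343 with that block and 2660 with array weights, and any diet 502 and 2371. With slide as a random block (estimated correlation within slides 0.0318), high fat against control gave 801 and any diet 1393. The random block kept all 20 named calls in each of the 3 comparisons. At an unadjusted p under 0.05 the counts were 3166, 3499 and 4439. The overlap of 15 became 8 with Cy5 alone, 7 with the first background fit, 4 with slide as a fixed block, 32 with array weights and 5 to 49 without 1 rat. Called lists numbered 0, 5 and 4 with an estimated correlation (0, 4 and 4 without control 6) and 3, 8 and 9 by fry, in the order of the report. The 3 by fry were amino acid catabolism, the urea cycle and conjugation (fry adjusted p = 0.00799, 0.0129 and 0.0129). With slide as a fixed block they numbered 7, 13 and 11 in place of 8, 13 and 14. Genes that reversed had not passed the test: Fasn in high protein against control with slide as a fixed block (-0.0434; -0.0168 to 0.507 without 1 rat), Pck1 there (-0.215 to 0.0586 without 1 rat, positive without high protein 1), Phgdh between the diets with slide as a fixed block (-0.0964), and Sds in high fat against control with slide as a fixed block (-0.232), array weights (-0.0686) and the first background fit (-0.00443; -0.134 to 0.264 without 1 rat). Apart from the smaller samples of the omissions, the cause was not tested. Of the 20 named calls of high protein against control, 9 were lost with processed signals, 8 with Cy5 alone, 7 with the deposited values, 9 with only the compared groups and 7 with the first background fit. Beyond the 20 of each comparison, a change of signal, background, filter, probes, block or arrays other than slide as a fixed block ended calls of Cps1, Hal, Crp, Nqo1 and Rgs5 in high protein against control. In high fat against control it did so for Angptl4, Cib2, Creb3l3, Slc27a5, Esam, Lipc, Psmc3, Ghr and Ambp, among others. Between the diets it did so for Fbp1, Ghr, Keap1, Lyz2, Mrc1, Nsdhl, Pmvk, Chac1, Serpina1, Sesn2, Slc10a1, Slc27a5 and Acadl, among others. The median shift of all genes under the alternatives reached 0.05 at most. Dim probes limit what was measured: 36564 features were tested without the filter and 17374 with signal on all arrays. Lists were not run with slide as a random block.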

Other observations

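Some gene groups outside the main accounts held single genes that changed while the list as a whole did not pass camera. The neutrophil list and its test were chosen only after the result was seen. In high fat livers 1 of 17 circadian clock genes, Usp2, rose over all genes, and adjusted over the list alone 5 rose and 4 fell (median 0.05, camera adjusted p = 0.382). Among 22 genes of the insulin and growth hormone axis 2 fell, Sgk1 (-1.42 ± 0.31) among them (2 rose and 5 fell adjusted over the list alone, camera adjusted p = 0.802). The 26 genes of triglyceride storage and lipoproteins included falls of Apoa4 (-1.11 ± 0.16) and the hepatic lipase gene Lipc (-0.32 ± 0.08), both also adjusted over the list alone (2, camera adjusted p = 0.802). Of 34 conjugation genes Nat8 (1.26 ± 0.27), the estrogen sulfotransferase gene Sult1e1 (0.86 ± 0.12) and Gstm7 (0.71 ± 0.12) rose and 1 fell (5 rose and 3 fell adjusted over the list alone, camera adjusted p = 0.615). Hspa4l of the heat shock list fell (-0.80 ± 0.14, -2.36 with processed signals and -1.22 with the deposited values), while the endothelial gene Esam rose by 0.35 ± 0.10 and the proteasome gene Psmc3 by 0.18 ± 0.05. With slide as a fixed block Esam no longer passed (0.27, adjusted p = 0.397), nor did Psmc3 (0.17, adjusted p = 0.221), Lipc (-0.28, adjusted p = 0.212), Nat8 (1.35, adjusted p = 0.052) and Sgk1 (-1.31, adjusted p = 0.0748). Leaving out 1 rat ended the call of Esam in 12, of Psmc3 in 9 and of Lipc in 4 of 19 omissions.

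In high protein livers the acute phase gene Crp rose by 0.43 ± 0.09 over control (adjusted p = 0.0402), the pericyte gene Rgs5 by 0.45 ± 0.08 and the quinone reductase gene Nqo1 by 0.63 ± 0.12 (1.29 with processed signals). Leaving out 1 rat ended the call of Crp in 11, of Nqo1 in 7 and of Rgs5 in 4 of 19 omissions, and slide as a fixed block ended those of Crp (0.34, adjusted p = 0.103), Nqo1 (0.49, adjusted p = 0.103) and Rgs5 (0.42, adjusted p = 0.0902). Against high fat livers Crp was higher by 0.54 ± 0.09 and Saa4 by 0.38 ± 0.11, 2 of 30 acute phase genes (2 adjusted over the list alone, camera adjusted p = 0.713). Of 10 gluconeogenesis genes 4 were higher with high protein, Mdh1 (0.82 ± 0.12), Gpd1 (0.55 ± 0.13) and Fbp1 (0.43 ± 0.10, but 0.13 and adjusted p = 0.444 with Cy5 alone) among them (4 adjusted over the list alone, camera adjusted p = 0.0721). Of 21 genes of serine synthesis and the amino acid response 3 were higher, Nupr1 (0.90 ± 0.17), Chac1 (0.58 ± 0.16) and Sesn2 (0.38 ± 0.10) (3 adjusted over the list alone, camera adjusted p = 0.0721). The growth hormone receptor gene Ghr (0.51 ± 0.07, but 0.20 and adjusted p = 0.107 as the mean over its probes) and Stat5b (0.48 ± 0.11) of the growth hormone axis were higher, as was the secreted protein gene Serpina1 (0.41 ± 0.09), while F9 was lower (-0.50 ± 0.10). Of 14 Kupffer cell and macrophage markers Lyz2 was higher (0.77 ± 0.22) and Mrc1 lower (-0.28 ± 0.08, but -0.16 and adjusted p = 0.334 as the mean over its probes). With slide as a fixed block all of these calls between the diets were lost except those of Ghr, Mdh1 and Nupr1, though each kept its direction and only 1 slide held both diets. Leaving out 1 rat ended the call of Mrc1 in 9, of Lyz2 in 7, of Chac1 in 7 and of Saa4 in 6 of 19 omissions.

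Some lists of stress, growth and signalling passed in none of the 3 comparisons. The lowest camera adjusted p was 0.388 for endoplasmic reticulum stress, 0.241 for heat shock, 0.769 for proliferation, 0.0738 for hepatocyte secreted proteins, 0.713 for the acute phase, 0.388 for the insulin and growth hormone axis, 0.382 for the circadian clock and 0.736 for triglyceride storage. Lists whose median, mean and test differed in sign were all among those that did not pass, such as fatty acid oxidation in high protein against control livers, with a median of -0.0079, a mean of -0.02 and a camera test pointing up (adjusted p = 0.947). In high protein against control livers the lists for fatty acid synthesis (0.05, adjusted p = 0.684), glycolysis (0.08, adjusted p = 0.0659) and gluconeogenesis (-0.09, adjusted p = 0.684) did not pass either. Neutrophil markers, 3 genes, had a median of 0.32 in control 6, within the range of the other 18 livers (-0.48 to 0.54).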
